A study of Mus musculus with 72 samples.

How the data were processed

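Bulk messenger RNA was sequenced from the dorsal (DH) and ventral (VH) hippocampus of male mice labelled with 2 C57BL/6 substrains, 6J and 6NJ, after 3 conditions (home cage, cue, shock and cue). The 12 groups held 6 libraries each. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and stranded mRNA libraries were sequenced as single-end reads of 75 bp. The deposited gene table held whole-number counts of reads for 55401 Ensembl genes, and per the submitters' processing notes HISAT2, featureCounts and the build GRCm38 were used. The columns of that table are those that featureCounts writes. A second deposited table held estimated counts for 119414 transcripts, with the columns that kallisto writes, and kallisto is named in the submitters' processing notes. FastQC and DESeq2 are named there too. Versions, the strand setting of the counting, filters and the fragment length given to kallisto are not given in the sources used here. Neither table was normalized, and every sample column of both was matched to a sample by its name.

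Groups were taken from the labels. Each library also carried a code of a number and a letter, shared by a DH and a VH library. The labels do not say whether the libraries of a group came from separate mice, so p-values measure only the spread between these libraries. Each of the 12 code numbers belonged to 1 strain label and 1 condition, with 3 codes for each number. A chi-square comparison of counts over genes with a summed count of at least 20 found no library deposited under several names: over the 180 pairs of libraries within groups, chi-square per degree of freedom was at least 4.5, with a median of 14.7.

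Symbols were found for 55141 of the 55401 gene identifiers, and coordinates came from the GENCODE vM21 annotation of GRCm38. Of the genes, 14866 had a count of 0 in every library. Library totals were 30330382 to 56258370 gene counts. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the low-count filter filterByExpr by group, estimateDisp, glmQLFit with robust estimation, and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene or transcript in the text comes from this test unless another tool is named. The model had 1 mean per group and no covariate. The 36 libraries of each region were fitted together, and the 72 libraries together for comparisons between regions, so that the groups shared 1 estimate of the spread. After filtering, 19647 genes were tested in DH, 19597 in VH and 20255 in both together. The common biological coefficient of variation was 0.118, 0.0999 and 0.112. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Estimated counts of transcripts were rounded to whole numbers and tested in the same way. CPM values are per library total scaled by TMM, and log2 CPM used a prior count of 2. Intervals of 95% used the degrees of freedom of the quasi-likelihood fit.

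Strain labels were compared in the home cage and as the mean of the 3 conditions, as 6NJ minus 6J. Within each strain label and region, the cue and the shock and cue groups were compared with the home cage and with each other. Interactions tested whether a response differed between strain labels. DH was compared with VH as the mean of all groups, and by strain label and by response to shock and cue. These comparisons, the alternatives below unless stated otherwise, the gene lists and the rule for naming genes were fixed before the data were examined. By that rule, each comparison named from the 12 higher and the 12 lower genes with the smallest p among those with adjusted p under 0.05, all genes of an interaction with fewer than 5, and any member of the gene lists; a comparison with no gene past the threshold named list members only. Transcripts were those of named strain genes.

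The 31 gene lists comprised 14 of function, 14 of cell types and 3 of neighbouring tissue. They were tested with camera from limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list. Of 775 tests, 196 passed with the preset value and 23 with the estimated correlation, and these 23 were among the 196. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. A symbol with several gene models was counted once for each model.

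The alternatives were RLE size factors, no low-count filter, a mean CPM of at least 1 as the filter, DESeq2 1.42.0, a fit of only the groups compared, limma-voom with the code number as a random effect, the code as a block between regions, the estimated correlation of lists, and a threshold of 0.01 for the overlap of regions. A choroid plexus covariate, leaving out codes with Lcn2 above 2 CPM, leaving out the DH library 40A and the mean of both strain labels were added after the data were seen. Each count of genes was also compared with counts from other splits of the same libraries: 40 splits within a region, 30 between regions and 24 for transcripts, the real one included. The code was tested on simulated data, in which counts were drawn from the means and totals of these libraries with known changes in seeded genes. For the mean strain label difference, 88% of genes changed 1.5-fold were recovered in DH among 19481 simulated genes and 90% in VH among 19432. With 50 changed genes for each fold size, 178 genes were called in DH, 6 of them wrongly, and 189 in VH, 11 of them wrongly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.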

Results

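Messenger RNA was measured by bulk sequencing in the hippocampus of male mice of 2 closely related C57BL/6 substrains, labelled 6J and 6NJ. The dorsal hippocampus (DH) and the ventral hippocampus (VH) gave separate libraries. Mice stayed in the home cage, received a cue without shock, or received shock together with the cue, as in fear conditioning, and the tissue was taken 30 min later. The 2 regions, 2 strain labels and 3 conditions made 12 groups of 6 libraries, 72 in all. Each library carried a code, such as 31A, and the same 36 codes occurred in DH and VH. Each code number belonged to 1 strain label and 1 condition, and each group held 2 numbers. Anything shared by the numbers of a strain label or condition could therefore not be separated from that label or condition. The consensus correlation of libraries with the same number, estimated with limma, was -0.0357 in DH and -0.0301 in VH. Total gene counts per library ranged from 30330382 to 56258370, and mitochondrial genes took 5.6% to 9.44% of them. All fold changes between strain labels are given as labelled 6NJ over labelled 6J.

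Genes known to differ in sequence between the substrains were examined first, as a check of the labels. Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase, was lower in the libraries labelled 6NJ, at 20.3 ± 1.15 CPM against 38 ± 1.87 CPM in those labelled 6J (SD, n = 36 each). Gabra2, the alpha 2 subunit of the GABA-A receptor, was at 120 ± 15.7 CPM in libraries labelled 6NJ and 267 ± 35.4 CPM in those labelled 6J. Crb1, a cell polarity gene, showed the opposite order, with 1.29 ± 0.43 CPM under the label 6NJ and 0.518 ± 0.205 CPM under 6J. As background, the C57BL/6J line is known for a deletion in Nnt and for low Gabra2 expression, and C57BL/6N lines for a mutation in Crb1. The libraries that held less Nnt and Gabra2 were those labelled 6NJ, which is against the labels. This held library by library: all 36 libraries labelled 6NJ lay below every library labelled 6J in Nnt, in Gabra2 and in Wdfy1, and all 36 lay above every library labelled 6J in mt-Tg. The samples are therefore named by their labels throughout, and every direction between strains below is a direction between labels.

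Nnt lies on chromosome 13 from 119335448 to 119408997 on the minus strand (ENSMUSG00000025453; GRCm38). A second gene model of Nnt, ENSMUSG00000116207, covers nearly the same exons, from 119335528 to 119408952, and the reads of the gene may be divided between them. Gabra2 lies on chromosome 5 from 70957597 to 71095849 (ENSMUSG00000000560, minus strand), and Crb1 on chromosome 1 from 139197056 to 139377100 (ENSMUSG00000063681, minus strand). The mitochondrial genome gave a further difference. The gene mt-Nd3 (MT, 9459 to 9806) was counted at 6.86 ± 4.49 CPM in libraries labelled 6NJ and 0.473 ± 0.446 CPM in those labelled 6J, whereas its nuclear pseudogene Gm28438 (chromosome 1, 24612775 to 24613119) was counted at 0.861 ± 1.9 and 7.66 ± 1.45 CPM (SD, n = 36 each). Over the 345 bases they share, the reference sequences of mt-Nd3 and Gm28438 differ by 1 substitution, T3C, numbered from the first base of mt-Nd3 and located at MT 9461. In the estimated counts of transcripts the order was the other way for Gm28438-201, at 40.3 CPM under the label 6NJ and 7.13 CPM under 6J in DH (log2 fold change 3.28 ± 0.844, adjusted p = 0.0243) and 32.3 and 2.83 CPM in VH (3.95 ± 0.855, adjusted p = 0.00719). The transcript mt-Nd3-201 did not pass in DH (0.18 ± 0.0607, adjusted p = 0.118) or in VH (0.09 ± 0.072, adjusted p = 0.711). Counts of these near-identical sequences can be exchanged between them by read assignment, and both are uncertain as expression levels.

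**Figure D1:**
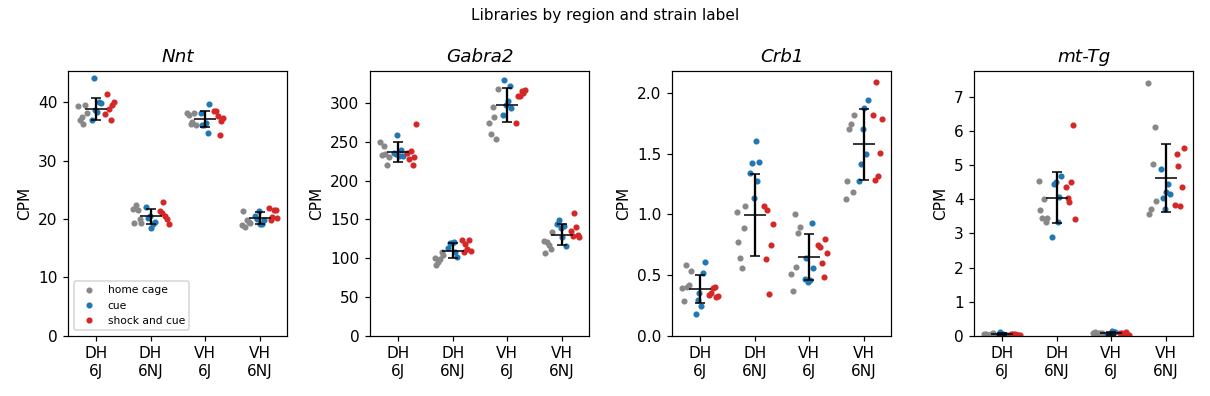
CPM of Nnt, Gabra2, Crb1 and mt-Tg (vertical axes) in each of the 72 libraries, arranged by region and strain label, with home cage, cue, and shock and cue in different colours; bars are the mean and SD over 18 libraries. The libraries labelled 6NJ held 20.3 ± 1.15 CPM of Nnt and those labelled 6J 38 ± 1.87 CPM, with no overlap.

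In the home cage, the strain labels differed in most of the genes above and, in DH, in genes such as Crhbp and Cort. In DH, Crhbp, which encodes a binding protein for corticotropin-releasing hormone, was higher under the label 6NJ (log2 fold change 0.83 ± 0.0917 SE, adjusted p = 1.74e-07), as were Cort, which encodes the interneuron peptide cortistatin (1.4 ± 0.163, adjusted p = 4.24e-07), the DNA sensor Aim2 (1.18 ± 0.137, adjusted p = 4.06e-07) and the stress-response transcription factor Atf4 (0.4 ± 0.0493, adjusted p = 1.35e-06). Wdfy1 (-1.25 ± 0.0458), Gabra2 (-1.24 ± 0.0495), Nnt (-0.87 ± 0.0478) and the imprinted gene Ndn (-0.64 ± 0.0759) were lower. In VH the same direction was seen for Aim2 (1.15 ± 0.135, adjusted p = 6.03e-07) and Atf4 (0.42 ± 0.0583, adjusted p = 1.29e-05), and the mitochondrial fusion gene Mfn2 was higher (0.24 ± 0.0327). Oprk1, the kappa opioid receptor, was lower in VH under the label 6NJ (-1.16 ± 0.18, adjusted p = 0.000146), beside Wdfy1 (-1.19 ± 0.0434), Nnt (-0.92 ± 0.0398) and Gabra2 (-1.24 ± 0.0612). In DH 183 of 19647 genes passed the test, 113 higher and 70 lower, and in VH 264 of 19597, 150 higher and 114 lower. Of the 16 gene models tested from the list of known substrain sequence differences, 1 was higher and 4 lower in DH, with the same counts adjusted over the list alone (camera adjusted p = 2.03e-10, and 2.47e-06 with an estimated correlation). In VH 2 of 14 were higher and 4 lower, again with the same counts adjusted over the list alone (adjusted p = 3.95e-12, and 1.75e-06 with an estimated correlation). Dentate granule cell markers were higher in VH under the label 6NJ in 3 of 11 genes, and in 6 adjusted over the list alone (adjusted p = 2.82e-07). Of the other cell type lists in VH, oligodendrocyte markers had a median of 0.333 (adjusted p = 5.84e-06), microglia markers of -0.14 and CA1 markers of -0.163 (adjusted p = 0.017 for both), with 0 members past the test. Adjusted over the list alone 0, 2 and 1 were lower. In DH the dentate and oligodendrocyte lists had medians of 0.233 and 0.196 (adjusted p = 0.00102 and 0.000844), with 0 members past the test, also adjusted over the list alone. These calls were lost (adjusted p = 0.365, 0.731, 0.977 and 0.093 in VH and 0.925 for both in DH with an estimated correlation). Fitting the 12 home cage libraries of a region alone gave 108 genes in DH and 59 in VH. DESeq2 called 298 in DH, and a fit with no low-count filter 171 in VH. In the groups labelled 6J, 6 codes, 4 in the cue groups and 2 in the home cage groups, held the acute-phase protein gene Lcn2 above 2 CPM in both regions. Without them, a choice made after the data were seen, 104 genes passed in DH and 371 in VH.

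Averaged over the 3 conditions, the labels differed in many more genes. In DH, Cort (1.49 ± 0.0942), Crhbp (0.7 ± 0.0525), the brain-expressed X-linked genes Bex1 (0.49 ± 0.0353) and Bex2 (0.39 ± 0.0288), and the neuronal calcium sensor Ncald (0.37 ± 0.0279) were higher under the label 6NJ, with adjusted p from 1.1e-14 to 1.43e-12. The peptide genes Npy (0.48 ± 0.0533, adjusted p = 4.39e-08) and Sst (0.29 ± 0.0543, adjusted p = 0.000311) were also higher in DH, while Vip was lower (-0.32 ± 0.0932, adjusted p = 0.0188). The neurotrophin gene Bdnf was higher under the label 6NJ in DH (0.35 ± 0.0484, adjusted p = 3.51e-06) and in VH (0.36 ± 0.0472, adjusted p = 1.22e-06). In VH, the RNA-binding protein gene Khdrbs1 (0.24 ± 0.0207), the cysteinyl-tRNA synthetase gene Cars (0.29 ± 0.0258), Mfn2 (0.21 ± 0.0189) and the nucleolin gene Ncl (0.22 ± 0.0198) were among the genes with the smallest p. In all, 2888 genes passed in DH (1583 higher, 1305 lower) and 1945 in VH (954 higher, 991 lower). Without the 6 codes with Lcn2 above 2 CPM, 1586 passed in DH and 1289 in VH.

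Gene groups moved with the strain label by small amounts. In DH, 9 of 12 oligodendrocyte markers were higher under the label 6NJ and all 12 adjusted over the list alone, among them Mbp (0.24 ± 0.0702), Mog (0.29 ± 0.0615) and Opalin (0.37 ± 0.0826), with a camera adjusted p = 1.95e-06 that was not kept (adjusted p = 0.84 with an estimated correlation). In VH 1 of the 12 was higher, and 8 adjusted over the list alone (median 0.261, adjusted p = 1.7e-06, and adjusted p = 0.608 with an estimated correlation). A list of neighbouring tissue and another cell type list were lower in DH: neocortical markers in 3 of 10, also adjusted over the list alone (median -0.196, adjusted p = 0.0256), and astrocyte markers in 4 of 11, and 5 adjusted over the list alone (median -0.079, adjusted p = 0.0478). Neither call was kept (adjusted p = 0.84 for both with an estimated correlation). In VH neither list passed (adjusted p = 0.323 and 0.0855). Dentate granule cell markers were higher in 5 of 11 genes in DH, 6 adjusted over the list alone, among them C1ql2 (0.51 ± 0.0907) and Plk5 (0.45 ± 0.113), with adjusted p = 0.000188 and adjusted p = 0.84 with an estimated correlation. In VH 4 of the 11 were higher, 7 adjusted over the list alone (adjusted p = 1.17e-05, and adjusted p = 0.591 with an estimated correlation). Of 36 subunits of mitochondrial complex I, 13 were higher in DH and none lower, 14 adjusted over the list alone, with Ndufa10 at 0.13 ± 0.0291 and Ndufs1 at 0.11 ± 0.0229 (adjusted p = 2.58e-05, and adjusted p = 0.84 with an estimated correlation). In VH 4 of the 36 were higher and none lower, also adjusted over the list alone, and the list did not pass (median 0.013, adjusted p = 0.441). In the DH home cage alone, 0 of the 36 passed, also adjusted over the list alone (median 0.017, camera adjusted p = 0.477). In VH, 7 of 33 rapid immediate early genes were higher and none lower, 8 adjusted over the list alone, including Egr4 (0.25 ± 0.05) and Atf3 (0.41 ± 0.117), with adjusted p = 0.000128 and adjusted p = 0.434 with an estimated correlation. In the VH home cage alone, 0 of the 33 passed, also adjusted over the list alone (median -0.001, camera adjusted p = 0.542). In DH 1 of the 33 was higher (Jun, 0.19 ± 0.0522) and 2 were lower (Egr2, -0.54 ± 0.124, and Arc, -0.25 ± 0.0682), with the same counts adjusted over the list alone. The substrain list kept its call in both regions (adjusted p = 0.000565 in DH and 0.000447 in VH with an estimated correlation), with 3 higher and 5 lower of 16 in DH and 3 higher and 4 lower of 14 in VH; adjusted over the list alone, 3 and 6 in DH and 3 and 4 in VH. Redox and NADPH enzymes, a list that holds Nnt, were higher in 2 and lower in 3 of 27 gene models in VH, 2 and 4 adjusted over the list alone (adjusted p = 0.00236, and adjusted p = 0.385 with an estimated correlation). In DH 0 were higher and 3 lower, also adjusted over the list alone, and the list did not pass (adjusted p = 0.303). Of the genes with a published substrain difference in coding sequence, Cyfip2 stayed near 0 (-0.01 ± 0.0305 in DH and 0.01 ± 0.0311 in VH).

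The strain label differences of DH and VH overlapped. Among 19270 genes tested in both regions, 1219 passed in both with the same sign and 0 with opposite signs, 651 of them higher and 568 lower under the label 6NJ. Independent lists would share 77.7 and 66.2 genes. Across genes, the log2 fold changes of DH and VH correlated with Pearson r = 0.7 and Spearman rho = 0.57; genes are not independent replicates, and the DH and VH libraries carried the same codes, so these are not separate sets of mice as far as the labels show.

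**Figure D2:**
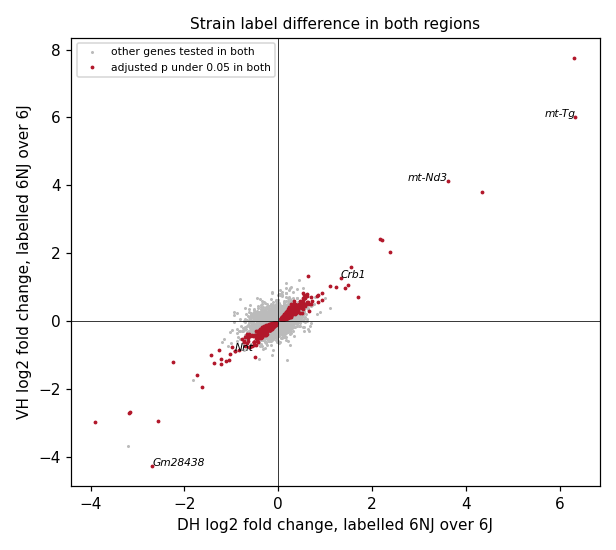
Log2 fold change of libraries labelled 6NJ over 6J in DH (horizontal axis) and VH (vertical axis), mean of 3 conditions, for 19270 genes; red points passed adjusted p under 0.05 in both regions. The 1219 red points have the same sign in both regions, and across genes r was 0.7.

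Single transcripts of Nnt and Gabra2 did not all follow the gene. The protein-coding transcript Nnt-206 (3339 nt) was at 30.8 CPM in DH under the label 6J and 13.1 CPM under 6NJ (log2 fold change -1.24 ± 0.0562, adjusted p = 2.77e-17), and in VH at 28.8 and 13.3 CPM (-1.12 ± 0.0576, adjusted p = 8.83e-16). The shorter Nnt-201 (3122 nt) was at 4.88 and 5.53 CPM in DH and did not pass (0.18 ± 0.205, adjusted p = 0.811). The coding transcript Gabra2-203 (5852 nt) was lower under the label 6NJ in DH (-1.22 ± 0.0369) and in VH (-1.35 ± 0.0456), whereas Gabra2-202, annotated as a retained intron, was higher, at 6.46 against 0.614 CPM in DH (3.44 ± 0.196, adjusted p = 1.38e-14) and 7.91 against 0.604 CPM in VH (3.7 ± 0.21, adjusted p = 1.27e-14). In all, 1641 of 56523 transcripts passed in DH (1115 higher, 526 lower) and 1218 of 55754 in VH (697 higher, 521 lower), and DESeq2 called 2516 and 1934. These are estimated counts, which divide reads between similar transcripts.

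Immediate early genes, which are transcribed within minutes of neuronal activity, were higher after the cue alone than in the home cage, in both regions and under both strain labels. No group was handled without a cue. Changes from the home cage after the cue, or after shock and cue, therefore could not be separated from effects of handling. In DH labelled 6J, Egr2 rose from 1.2 ± 0.49 to 10.9 ± 1.81 CPM (SD, n = 6; log2 fold change 3.18 ± 0.222 SE, adjusted p = 7.38e-12), Arc, which encodes a cytoskeletal protein of synapses, from 106 ± 15.2 to 380 ± 38 CPM (1.85 ± 0.122, adjusted p = 6.12e-12), and Fos from 5.84 ± 1.75 to 31.3 ± 6.4 CPM (2.43 ± 0.24, adjusted p = 5.97e-08). In DH labelled 6NJ, Egr2 rose by 3.05 ± 0.228, Arc by 1.59 ± 0.121, Fosb by 1.64 ± 0.135 and the salt-inducible kinase Sik1 by 1.14 ± 0.132. In VH, Fos rose by 2.34 ± 0.169 under the label 6J and by 2.42 ± 0.168 under 6NJ, and Arc by 1.62 ± 0.0821 and 1.76 ± 0.0825. Of 33 rapid immediate early genes, 27 rose in DH labelled 6J, 25 in DH labelled 6NJ, 26 in VH labelled 6J and 28 in VH labelled 6NJ, and none fell. Adjusted over the list alone the counts were 31, 29, 29 and 30. The list passed camera in all 4, with adjusted p of 3.05e-05, 5.49e-06, 9.25e-06 and 5.05e-07 with an estimated correlation. Npas4, a neuron-specific immediate early gene, was at 16.4 ± 4.67 CPM in the home cage and 22.5 ± 3.86 CPM after the cue in DH labelled 6J (SD, n = 6; 0.47 ± 0.146) and did not pass over all genes (adjusted p = 0.0517). Over the whole transcriptome, the cue changed 1157 genes in DH labelled 6J (748 higher, 409 lower), 463 in DH labelled 6NJ (344 higher, 119 lower), 2518 in VH labelled 6J (1524 higher, 994 lower) and 2519 in VH labelled 6NJ (1365 higher, 1154 lower). A fit of only the groups compared gave 515, 268, 2390 and 893 genes in the same order. A fit with no low-count filter gave 734, 286, 1542 and 1484. With the 6 codes with Lcn2 above 2 CPM left out, the cue changed 31 genes in DH and 47 in VH labelled 6J, from 2 cue and 4 home cage libraries.

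Other gene groups rose with the cue as well. Later activity-induced genes rose in 9 of 22 in DH labelled 6J, 7 in DH labelled 6NJ, 10 in VH labelled 6J and 15 in VH labelled 6NJ, with Homer1, Dusp5, Dusp6 and Arl4d among them in all 4. Homer1, a scaffold of metabotropic glutamate receptors, rose by 0.55, 0.45, 0.52 and 0.61 on the log2 scale in that order. Adjusted over the list alone, 11, 12, 12 and 15 rose and 1, 1, 2 and 1 fell; all 4 calls held with an estimated correlation (adjusted p = 0.00326, 0.0109, 0.015 and 0.000545). Glucocorticoid target genes rose in 10, 8, 9 and 8 of 23, with 10, 9, 10 and 9 adjusted over the list alone, among them Sgk1 (0.8, 0.69, 0.73 and 0.74) and Ddit4 (0.49, 0.49, 0.54 and 0.55). The list passed camera in all 4, but not with an estimated correlation (adjusted p = 0.141, 0.536, 0.404 and 0.7 with an estimated correlation). Heat shock chaperones rose in 6, 3, 9 and 6 of 15, with 12, 9, 11 and 6 adjusted over the list alone, and Dnajb1 rose in all 4 (0.55, 0.36, 0.58 and 0.36). Their calls were lost as well (adjusted p = 0.289, 0.415, 0.404 and 0.7 with an estimated correlation). Chaperones of the endoplasmic reticulum rose in 8 of 15 gene models in DH and 9 in VH labelled 6J, among them Hspa5 (0.81 and 0.68). Under the label 6NJ none of them passed in DH, and in VH 1 rose and 1 fell. Adjusted over the list alone 13 rose in DH and 12 in VH labelled 6J, with 1 falling in VH, and under the label 6NJ 0 in DH and 3 in VH, with 1 falling in VH. The list passed camera in all 4 and was lost in each (adjusted p = 0.476 and 0.624 for the label 6J and 0.916 and 0.892 for 6NJ with an estimated correlation). The difference between the labels in this response was not called for any gene by edgeR. Without the 6 codes with Lcn2 above 2 CPM, the list medians of the cue response under the label 6J were near 0. They went from 0.422 to 0.001 in DH and from 0.235 to -0.004 in VH for the glucocorticoid targets, from 0.228 to 0.02 and from 0.277 to 0.066 for the heat shock chaperones, and from 0.418 to 0.065 and from 0.305 to 0.028 for the chaperones of the endoplasmic reticulum. The medians of the rapid immediate early genes went from 0.676 to 0.583 in DH and from 0.546 to 0.504 in VH.

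Fewer genes fell than rose with the cue. Cirbp, a cold-inducible RNA-binding protein gene, fell in DH labelled 6J (-0.67 ± 0.107, adjusted p = 0.000146) and in VH labelled 6J (-0.69 ± 0.101, adjusted p = 3.11e-05). The mitochondrial import gene Timm44 fell in VH labelled 6J (-0.31 ± 0.0435). The endothelial transcription factor genes Sox17 and Sox18 fell in DH labelled 6NJ (-0.62 ± 0.107 and -0.74 ± 0.123), and Sox17 fell in VH labelled 6NJ (-0.67 ± 0.11). The transferrin receptor gene Tfrc fell in DH labelled 6J (-0.32 ± 0.0567). Mitochondrially encoded genes of VH fell in 4 of 15 genes under each label, 8 and 7 adjusted over the list alone, with mt-Nd5 at -0.33 and -0.36 (adjusted p = 0.624 and 0.882 with an estimated correlation). Markers of other cell types also differed in DH labelled 6J after the cue: oligodendrocyte markers had a median of -0.257, with 1 of 12 lower and 6 adjusted over the list alone, and 5 blood genes a median of 0.849, with 0 past the test and 3 higher adjusted over the list alone (adjusted p = 0.476 for both with an estimated correlation). Leptomeningeal genes had a median of 0.567 in the same libraries, with 0 of 10 past the test, also adjusted over the list alone (adjusted p = 0.708 with an estimated correlation). Microglia markers in VH labelled 6NJ were higher in 1 of 11, and 4 adjusted over the list alone (adjusted p = 0.882 with an estimated correlation). Lcn2 in DH labelled 6J after shock and cue was at 0.0595 ± 0.04 CPM (SD, n = 6), and none of the 6 codes with Lcn2 above 2 CPM was in that group.

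Shock together with the cue raised the same kinds of genes over the home cage. Egr2 reached 10.3 ± 2.44 CPM in DH labelled 6J and 6.6 ± 1.74 CPM in DH labelled 6NJ (SD, n = 6; log2 fold change 3.09 ± 0.222 and 2.89 ± 0.228 SE over the home cage). Arc rose by 1.74 ± 0.121 and 1.57 ± 0.121 in DH and by 1.49 ± 0.0819 and 1.57 ± 0.0822 in VH, for the labels 6J and 6NJ. Fos rose by 2.47 ± 0.24 and 2.2 ± 0.237 in DH and by 2.25 ± 0.169 and 2.3 ± 0.168 in VH. The clock and glucocorticoid-responsive gene Per1 rose in DH labelled 6J (0.56 ± 0.0667, adjusted p = 9.19e-07), and Nr4a2, an orphan nuclear receptor gene, in DH labelled 6NJ (0.71 ± 0.0874, adjusted p = 2.77e-06). Rapid immediate early genes rose in 25 of 33 in DH labelled 6J, 26 in DH labelled 6NJ, 25 in VH labelled 6J and 26 in VH labelled 6NJ, and 27, 29, 28 and 30 adjusted over the list alone; the list held with an estimated correlation in all 4 (adjusted p = 6.83e-06, 4.06e-05, 4.19e-07 and 8.54e-07). Later activity-induced genes rose in 9, 8, 5 and 9 of 22, and Lingo1 and Mapk4 fell in VH labelled 6NJ (-0.21 and -0.24). Adjusted over the list alone, 10, 9, 14 and 13 rose and 1, 0, 2 and 2 fell, and the list held as well (adjusted p = 0.00648, 0.0235, 0.00204 and 0.00891 with an estimated correlation). In DH 345 genes changed under the label 6J (252 higher, 93 lower) and 701 under 6NJ (451 higher, 250 lower); in VH 610 (361 higher, 249 lower) and 1696 (893 higher, 803 lower). A fit of only the groups compared gave 217, 555, 355 and 863 genes in that order. With no low-count filter the counts were 205, 385, 360 and 1036, and DESeq2 called 927 in VH labelled 6J. Without the 6 codes with Lcn2 above 2 CPM, 178 genes changed in DH and 331 in VH under the label 6J.

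Sgk1 rose by 0.76 ± 0.0774 in VH labelled 6NJ (adjusted p = 2.09e-08), and the glucocorticoid targets rose in 8, 10, 8 and 9 of 23 in the order given for the immediate early genes. Lcn2 fell in both regions labelled 6J (-5.67 in DH and -5.5 in VH), where 2 home cage codes had high Lcn2. Adjusted over the list alone 10, 11, 9 and 9 rose and 2, 0, 5 and 1 fell. In DH and VH labelled 6J the median log2 fold change of the list was -0.05 and -0.023 and the mean -0.204 and -0.23, while camera called it upward, and no call of the list was kept (adjusted p = 0.756, 0.202, 0.8 and 0.222 with an estimated correlation). Without the 6 codes with Lcn2 above 2 CPM, these medians were 0.141 and 0.087 and the means 0.075 and 0.098. In DH labelled 6NJ Pdgfb (-0.42 ± 0.0695), Sox18 (-0.73 ± 0.123) and Foxq1 (-0.66 ± 0.112) fell, as did Tfrc (-0.33 ± 0.0564). Of 13 endothelial and mural cell markers 0 passed there, with 1 lower adjusted over the list alone (median -0.061, adjusted p = 0.0192, and adjusted p = 0.485 with an estimated correlation). In VH labelled 6NJ the small GTPase gene Rab34 fell by 0.47 on the log2 scale and the deubiquitinase gene Usp2 by 0.34. Ependymal genes rose in 3 of 8 in VH labelled 6J, 5 adjusted over the list alone, among them Foxj1 (0.67) and Dynlrb2 (0.8), with adjusted p = 7.3e-05 and adjusted p = 0.201 with an estimated correlation. In the same libraries the choroid plexus list had a median log2 fold change of 1.768 with 0 of 12 genes past the test, also adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.8 with an estimated correlation). Interneuron markers rose in 2 of 14 in VH labelled 6NJ, 5 adjusted over the list alone (adjusted p = 0.00351, and adjusted p = 0.396 with an estimated correlation).

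**Figure D3:**
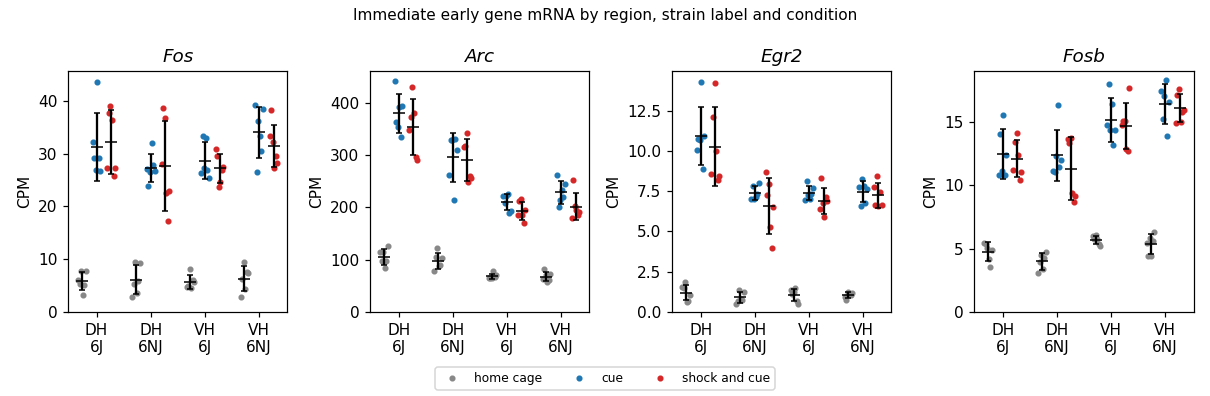
CPM of Fos, Arc, Egr2 and Fosb (vertical axes) in the 72 libraries by region, strain label and condition; points are libraries and bars the mean and SD of 6. Every home cage group lies below its cue and its shock and cue groups, with Fos in DH labelled 6J at 5.84 ± 1.75 CPM in the home cage, 31.3 ± 6.4 CPM after the cue and 32.3 ± 6.07 CPM after shock and cue.

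The responses under the 2 strain labels, which share no library, overlapped. The cue changed 305 genes with the same sign under both labels in DH and 1238 in VH, where independent lists would share 15.6 and 164.7, and none with opposite signs. For shock and cue the numbers were 183 in DH and 355 in VH, with 7 and 26.7 for independent lists and 1 gene of opposite sign in VH. Across genes, the log2 fold changes under the 2 labels correlated with r = 0.49 and 0.55 for the cue and 0.36 and 0.38 for shock and cue in DH and VH (rho = 0.5, 0.63, 0.4 and 0.5).

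The comparison of shock and cue with the cue alone addressed what the shock added. Fos differed by 0.04 (95% interval -0.39 to 0.48) on the log2 scale in DH labelled 6J, and Fosb by -0.04 (-0.3 to 0.21). Over the 33 rapid immediate early genes, the intervals stayed within ±1 on the log2 scale for 32 genes in DH labelled 6J, 33 in DH labelled 6NJ, 32 in VH labelled 6J and 33 in VH labelled 6NJ. In VH labelled 6NJ the list had a median of -0.1, with 0 of 33 past the test, also adjusted over the list alone (camera adjusted p = 8.64e-05, and adjusted p = 0.43 with an estimated correlation). No gene passed edgeR in any of these 4 comparisons, and 1896, 1399, 1465 and 1218 genes had an unadjusted p under 0.05; DESeq2 called 3, 0, 1 and 0 genes and limma-voom with code number as a random effect 0 in each. With both strain labels averaged, the count was 0 in both regions, with 1997 genes in DH and 1426 in VH at an unadjusted p under 0.05. In simulated data for this comparison in DH labelled 6J, 80% of genes changed 2-fold and 56% of those changed 1.5-fold were recovered. These shares came from 50 changed genes for each fold size and would be lower if few genes differed. Across genes the shock minus cue log2 fold changes under the 2 labels correlated with r = -0.02 in DH and 0.07 in VH (rho = 0.06 in both).

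Several gene lists were lower after shock and cue than after the cue alone in the libraries labelled 6J, with no member past the test over all genes. The glucocorticoid targets had a median of -0.163 in DH and -0.162 in VH, and 11 and 7 of 23 were lower adjusted over the list alone, with Hif3a at -0.78 ± 0.298 and Klf9 at -0.16 ± 0.0522 in DH. The heat shock chaperones had medians of -0.162 and -0.143, and 12 and 8 of 15 were lower adjusted over the list alone, with Hsph1 at -0.31 ± 0.076 in DH. The chaperones of the endoplasmic reticulum had medians of -0.295 and -0.205 and 0 of 15 past the test adjusted over the list alone. camera called the 3 lists in both regions, and none with an estimated correlation (adjusted p = 0.506, 0.506 and 0.518 in DH and 0.355 for each in VH with an estimated correlation). Without the 6 codes with Lcn2 above 2 CPM, the 3 medians were 0.118, 0.013 and 0.093 in DH and 0.053, 0.047 and 0.086 in VH. Under the label 6NJ, where no code had that level, the medians were 0.08 and 0.017 for the glucocorticoid targets and 0.131 and 0.163 for the chaperones of the endoplasmic reticulum in DH and VH. For the heat shock chaperones the median was 0.047 in both regions. In the 3 lists 0 members passed, also adjusted over the list alone. The chaperones of the endoplasmic reticulum passed camera there in the upward direction, but not with an estimated correlation (adjusted p = 0.831 in DH and 0.632 in VH with an estimated correlation). The same was seen for the glucocorticoid targets in DH and the heat shock chaperones in VH (adjusted p = 0.831 and 0.657 with an estimated correlation). Mitochondrial lists were higher in DH labelled 6NJ, with no member past the test over all genes. Mitochondrially encoded genes had a median of 0.257 (camera adjusted p = 2.59e-08), with 8 of 15 higher adjusted over the list alone. Complex I subunits had a median of 0.097 (camera adjusted p = 2.19e-10), with 0 of 36 adjusted over the list alone. Neither call was kept (adjusted p = 0.817 and 0.831 with an estimated correlation). Markers of other cell types differed as well in the libraries labelled 6J. Oligodendrocyte markers had medians of 0.209 in DH and 0.273 in VH (adjusted p = 0.518 and 0.355 with an estimated correlation), and 0 of 12 passed, with 4 higher in DH and 0 in VH adjusted over the list alone. Choroid plexus genes in VH had a median of 1.373, with 0 of 12 past the test, also adjusted over the list alone (adjusted p = 0.466 with an estimated correlation). Under the label 6NJ, microglia markers had medians of -0.121 in DH and -0.168 in VH. Of these 11 markers 0 passed, also adjusted over the list alone (adjusted p = 0.831 and 0.632 with an estimated correlation).

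Whether the responses differed between strain labels was tested as an interaction. For single genes such as Fos, Arc and Egr2 no difference between labels was called: over the 33 rapid immediate early genes, the difference in the response to the cue lay between -0.41 and 0.41 on the log2 scale in DH and between -0.23 and 0.46 in VH. For shock and cue against the home cage it lay between -0.42 and 0.84 in DH and between -0.52 and 0.81 in VH, and for shock and cue against the cue between -0.39 and 1.24 in DH and between -0.28 and 0.49 in VH. The highest value, 1.24 (95% interval 0.63 to 1.85), was that of Maff, which did not pass over all genes (adjusted p = 0.543). No gene passed edgeR for the response to the cue, to shock and cue, or for shock and cue against the cue. In DH 621, 860 and 1369 genes had an unadjusted p under 0.05, and in VH 539, 817 and 1216. DESeq2 called 0, 0 and 1 gene in DH and 0, 1 and 0 in VH, and limma-voom with code number as a random effect 0 in each. In simulated data for the interaction with shock and cue, 68% of genes with a 2-fold difference were recovered in DH and 86% in VH. These shares too came from 50 changed genes for each fold size and would be lower if few genes differed. Among gene lists, the response of the circadian clock genes to the cue in DH was more negative under the label 6NJ (median difference -0.142, adjusted p = 1.17e-07, and 0.0199 with an estimated correlation), with 0 of 17 past the test and 3 lower adjusted over the list alone, namely Per2 (-0.39 ± 0.118), Per3 (-0.39 ± 0.136) and Bhlhe40 (-0.34 ± 0.111). The response of CA1 pyramidal cell markers to shock and cue in VH was more positive under the label 6NJ (median difference 0.185, adjusted p = 0.00185, and 0.037 with an estimated correlation), with 0 of 9 past the test and 0 adjusted over the list alone. The median response was -0.2 under the label 6J, with 1 of 9 lower and 2 adjusted over the list alone (adjusted p = 0.0379, and adjusted p = 0.201 with an estimated correlation), and 0.051 under 6NJ, with 0 past the test and 0 adjusted over the list alone (adjusted p = 0.821). In the home cage the list had a median of -0.163 under the label 6NJ relative to 6J, with 0 of 9 past the test and 1 lower adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.093 with an estimated correlation). The list of substrain sequence differences had a median of 0.084 in the same comparison (adjusted p = 0.00544, and 0.0401 with an estimated correlation), with 0 of 14 past the test and 0 adjusted over the list alone. In shock and cue against the cue, the chaperones of the endoplasmic reticulum had medians of 0.439 in DH and 0.369 in VH, and 0 of 15 passed, with 9 and 12 higher adjusted over the list alone (adjusted p = 0.327 and 0.442 with an estimated correlation). Without the 6 codes with Lcn2 above 2 CPM these medians were 0.065 and 0.058. Oligodendrocyte markers had medians of -0.268 in DH and -0.22 in VH in that comparison, with 0 of 12 past the test, also adjusted over the list alone (adjusted p = 2.51e-06 and 0.00435, and adjusted p = 0.466 and 0.535 with an estimated correlation).

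Between the regions, receptors and markers of several cell types differed. The axon guidance receptor genes Epha5 (log2 fold change, DH over VH, 0.71 ± 0.0271) and Epha7 (1.36 ± 0.0515) and the potassium channel genes Kcnab1 (0.65 ± 0.0267) and Kcnd2 (0.57 ± 0.0247) were higher in DH. The signalling gene Wnt7b (-0.77 ± 0.0262), the NMDA receptor subunit Grin3a (-1.06 ± 0.0407), the adhesion gene Cadm1 (-0.88 ± 0.0346) and the potassium channel Kcnj16 (-1.1 ± 0.0419) were higher in VH. Adjusted p for these genes lay between 8.6e-36 and 5.06e-31. All 11 dentate granule cell markers were higher in DH, among them Prox1 (0.75 ± 0.0603) and Lct (2.12 ± 0.0931), as were all 12 oligodendrocyte markers, with Mbp at 0.83 ± 0.067, and the counts adjusted over the list alone were the same. Of 9 CA2 markers 7 were higher in DH and Necab2 was lower (-0.74 ± 0.0488), with the same counts adjusted over the list alone. Interneuron markers were lower in DH in 8 of 14 genes and higher in 2, again the same adjusted over the list alone, with Sst at -0.57 ± 0.041 and Kit at -1.09 ± 0.0545. None of these 4 lists kept its call (adjusted p = 0.279, 0.279, 0.279 and 0.433 with an estimated correlation). Of 9 CA1 markers 4 were higher and 3 lower in DH, and of 8 CA3 markers 4 were higher and 1 lower, with the same counts adjusted over the list alone, and neither list passed camera (adjusted p = 0.494 and 0.282). All 12 choroid plexus genes were higher in DH, also adjusted over the list alone, although the list did not pass camera (adjusted p = 0.0914), with Ttr at 1.92 ± 0.637. Of 8 thalamus markers 4 were higher and 2 lower in DH, also adjusted over the list alone, with Prkcd at 2.12 ± 0.108 (median 0.166, adjusted p = 0.188). Of 10 leptomeningeal genes 1 was higher and 1, Dcn, was lower in DH (-2.38 ± 0.135), also adjusted over the list alone. The list had a median of 0.103, a mean of -0.109 and an adjusted p = 0.975. In all, 12888 of 20255 genes differed, 6633 higher and 6255 lower in DH.

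The DH library 40A of the cue group labelled 6NJ stood between the regions. On an axis with the mean of DH at 0 and of VH at 1, taken over the 12888 genes, it lay at 0.528, while the other 35 DH libraries lay between -0.363 and 0.26 and the VH libraries between 0.628 and 1.316. The lowest VH library was 40A, with the same code.

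**Figure D4:**
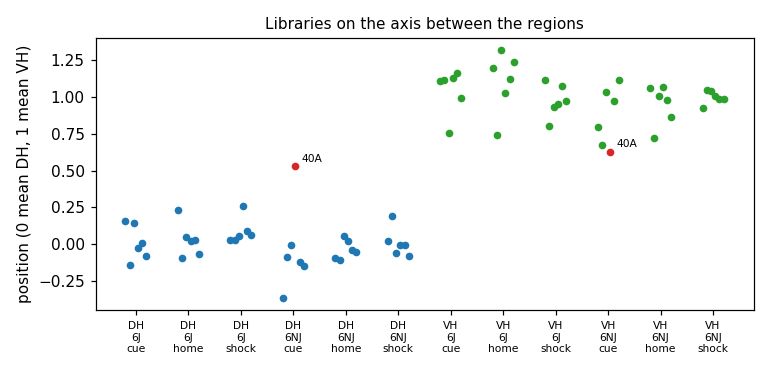
Position of each library (vertical axis, no unit) on the axis from the mean of DH (0) to the mean of VH (1) over 12888 genes, by group; the 2 libraries with code 40A are in red. The DH library 40A lies at 0.528, above the other DH libraries, which end at 0.26.

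For a dependence of the region difference on the strain label, 1 gene passed edgeR. Among 30 splits of the libraries, the real one included, 2 called as many genes, and the highest other split called 98. Acvr1c, a receptor of the activin and TGF-beta family (ENSMUSG00000026834, chromosome 2, 58267453 to 58357895, minus strand), had a higher ratio of DH over VH under the label 6NJ (0.38 ± 0.0633, adjusted p = 0.00162). DESeq2 also called 1 gene, and without the DH library 40A, a choice made after the data were seen, edgeR called 2. The rapid immediate early genes had a median of -0.105, with 0 of 33 past the test and 6 lower adjusted over the list alone (adjusted p = 4.22e-11, and adjusted p = 0.0942 with an estimated correlation). For the response to shock and cue against the home cage, no gene passed edgeR for a difference between the regions. At an unadjusted p under 0.05 there were 2104 genes, and DESeq2 called 0. With the code as a block 14 genes passed, so the count of 0 depended on treating DH and VH libraries as unpaired. The labels do not say whether DH and VH libraries with the same code came from the same mouse. The rapid immediate early genes had a median difference of 0.022 (adjusted p = 0.715), with 0 of 33 past the test and 2 higher in DH adjusted over the list alone. Complex I subunits had a median of 0.112, with 0 of 36 past the test, also adjusted over the list alone (adjusted p = 5.14e-09, and adjusted p = 0.753 with an estimated correlation). In simulated data with 50 changed genes for each fold size, 74% of genes with a 2-fold difference were recovered in this comparison. The share would be lower if few genes differed.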

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

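The tests of the strain labels, of library 40A and of the Lcn2 codes in this part were chosen after those results had been seen, while the comparisons with other splits of the libraries were planned.

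Nnt, Gabra2 and Wdfy1 mRNA were lower in the libraries labelled 6NJ, against what is known of Nnt and Gabra2 in the substrains. Single libraries with a wrong strain label are argued against by 0 of 72 libraries on the side of the other label in Nnt, Gabra2, Wdfy1 or mt-Tg. The ratio of library totals was 1.05 (6NJ to 6J), beside a ratio of 0.534 for Nnt CPM. CPM are already scaled by library totals, so this comparison cannot decide on a difference in depth. An exchange of the strain labels over the whole series cannot be told apart from labels as given by mt-Nd3 and Gm28438, which differ by a base (T3C), since the tables go both ways: in 70 of 72 libraries the one with more gene counts was mt-Nd3 under the label 6NJ and Gm28438 under 6J, but estimated counts of the transcript Gm28438-201 were higher under 6NJ, at 40.3 against 7.13 CPM in DH and 32.3 against 2.83 CPM in VH. The remaining libraries by gene counts were DH 41B of the home cage group and DH 39C of the shock and cue group labelled 6NJ, where Gm28438 stood far above the other 5 libraries, at 8.95 against at most 0.403 CPM and 8.07 against at most 0.666 CPM. Genotypes were not analysed here, so exchanged labels, a substrain difference as labelled, and effects of reads that differ from the reference sequence of C57BL/6J, stay open.

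The DH library 40A of the cue group labelled 6NJ lay at 0.528 on the axis from DH (0) to VH (1), and the highest other DH library at 0.26. An exchange of the DH and VH labels of code 40A is argued against by the VH library 40A, which lay at 0.628, outside the range of the other DH libraries. The same-code chi-square per degree of freedom between DH and VH was 6.9 for 40A, and 25.7 or more for every other code. Tissue or RNA of both regions in the 40A libraries is a candidate explanation: the genes higher in DH put the DH library 40A at 0.409, between the other DH libraries (up to 0.384) and the VH libraries other than 40A (from 0.582), and those higher in VH put it at 0.639, between 0.292 and 0.697. The margin of 0.409 over 0.384 is small, the comparison was set up with these positions known, and no biological explanation was tested.

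In the libraries labelled 6J, the glucocorticoid, heat shock and ER stress chaperone lists were lower after shock and cue than after the cue alone. Choroid plexus tissue in the dissection is argued against as the whole cause, since with a choroid plexus covariate 6 of 6 list medians kept their sign and at least 0.5 of their size, at -0.164, -0.155 and -0.279 in DH and -0.143, -0.137 and -0.218 in VH. Without the 6 codes with Lcn2 above 2 CPM, 0 of 6 medians did so, which is consistent with a pattern that lies in these codes. Lcn2 is itself 1 of the 23 glucocorticoid genes, the codes were picked after their expression had been seen, and 4 of the 6 cue libraries are among them, so this shows where the pattern lies and not what made it. A condition of single mice, such as illness or stress before the experiment, was not tested and stays open.

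Gaps of single libraries were examined in 156 combinations of 12 groups and 13 measures. In 18 of these, the gap of a library to the nearest of the others was large for the range of the group. For normally distributed values chance gives about 1 in 20, and low counts need not follow that distribution. The VH library 34B (6J, cue) had the highest total, 56.3 M counts (M, mega), against 36.7 M or less in its group. The VH library 32B (6J, cue) had the lowest mitochondrial share of its group, 6.15% against 7.18% or more. On the axis from DH to VH, DH 33A (6J, shock and cue) lay at 0.26 and DH 37B (6NJ, shock and cue) at 0.194. Arc was at 252 CPM in VH 37B (6NJ, shock and cue), Fos at 43.7 CPM in DH 34A (6J, cue) and Fosb at 16.4 CPM in DH 40A (6NJ, cue). Gabra2 was at 259 CPM in DH 32C (6J, cue), 273 CPM in DH 33C (6J, shock and cue) and, lowest of its group, 275 CPM in VH 31A (6J, shock and cue). Wdfy1 was lowest in DH 41B (6NJ, home cage), at 17.8 CPM. For mt-Nd3 the libraries were DH 34A (6J, cue) at 2.03 CPM, DH 39B (6NJ, shock and cue) at 8.52 CPM, VH 31C (6J, shock and cue) at 2.18 CPM and VH 40C (6NJ, cue) at 32.2 CPM, where the others of the group ended at 6.57 CPM. For mt-Tg it was DH 32B (6J, cue), at 0.117 CPM. Libraries labelled 6J held 0 to 6 counts of mt-Tg, so this gap is one of a few reads.

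Tests of the difference between groups itself called 1 gene and 3 lists. The ratio of DH over VH of Acvr1c was higher under the label 6NJ by 0.38 ± 0.0633 on the log2 scale (edgeR adjusted p = 0.00162). In that comparison 2 of 30 splits of the libraries, the real one included, called as many genes, so chance stays open. The cue response of the circadian clock list in DH differed by a median of -0.142 between the labels (adjusted p = 0.0199 with an estimated correlation). In VH the response to shock and cue differed by a median of 0.185 for CA1 pyramidal cell markers and of 0.084 for the list of substrain sequence differences (adjusted p = 0.037 and 0.0401 with an estimated correlation). In the VH home cage, from which that response was taken, the medians under 6NJ relative to 6J were -0.163 and -0.174. List tests were adjusted only within a comparison and no member of these lists passed over all genes, so chance stays open for the lists as well.

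Other splits of the same libraries were compared with the real one. The real split called more genes than any other for the strain label difference in the DH home cage (183 genes, highest other split 10, 1 of 40 as large). The same held for its mean in DH (2888, highest other 1) and VH (1945, highest other 0). In DH it held for the cue under 6J (1157, highest other 218) and 6NJ (463, highest other 51) and for shock and cue under 6J (345, highest other 44) and 6NJ (701, highest other 2). In VH it held for the cue under 6J (2518, highest other 1596) and 6NJ (2519, highest other 1936) and for shock and cue under 6J (610, highest other 6). It also held for the region difference (12888, highest other 5240, 1 of 30 as large) and the transcripts of DH (1641, highest other 1, 1 of 24) and VH (1218, highest other 3). With 40 splits or fewer for each of many comparisons, this makes chance less likely and does not exclude it. The splits within a region also moved single libraries and not whole code numbers.

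Another split called more genes than the real one in 3 comparisons, where chance stays open. These were the strain label difference in the VH home cage (264, highest other 443, 2 of 40 as large), shock and cue under 6NJ in VH (1696, highest other 2087, 2 of 40) and region by strain label (1, highest other 98, 2 of 30). Where edgeR called 0 genes, every split is as large by construction (40 of 40, and 30 of 30 for region by shock and cue). For shock and cue against the cue, the highest other split called 41 genes under 6J and 8 under 6NJ in DH, and 1 and 0 in VH. For the interactions of the strain label with the cue, with shock and cue and with shock and cue against the cue, it called 399, 719 and 0 genes in DH and 72, 1298 and 1 in VH, and for region by shock and cue 1. Splits that mix the labels or conditions unevenly carry part of the known differences, and what lies behind the high counts was not tested.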

How the results depend on the processing

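The choroid plexus covariate, the fits without the Lcn2 codes or without the DH library 40A, and the mean of both strain labels were chosen after the data were seen; the other alternatives were planned. All 27 counts of genes or transcripts stayed within 1.5 times the reported count with RLE size factors and with a mean CPM of at least 1 as the filter, and so did all 22 counts refitted with limma-voom with the code number as a random effect or with the choroid plexus covariate. Of 7794 values of single genes under the alternatives, 7303 kept their direction and their side of the threshold, 488 kept only the direction and 3 were reversed.

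With no low-count filter, which tests more genes, the cue changed 734 genes under 6J and 286 under 6NJ in DH, and 1542 and 1484 in VH. Shock and cue changed 205 and 385 in DH and 360 and 1036 in VH, the VH home cage strain difference had 171 genes, and shock and cue against the cue 1 gene under 6J in DH. Fits of only the groups compared, with fewer libraries, gave 108 genes in DH and 59 in VH for the home cage strain difference, 515 and 268 for the cue in DH and 893 under 6NJ in VH, and 217 for shock and cue under 6J in DH, 355 under 6J in VH and 863 under 6NJ in VH.

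DESeq2 called 298 genes for the DH home cage strain difference, 927 for shock and cue under 6J in VH, 3 and 1 for shock and cue against the cue under 6J in DH and VH, 1 for strain by shock and cue against the cue in DH, 1 for strain by shock and cue in VH, and 2516 and 1934 transcripts in DH and VH; the cause was not tested. Without the Lcn2 codes, counts were 104 and 371 (home cage strain difference, DH and VH, in place of 183 and 264), 1586 and 1289 (mean strain difference, DH and VH), 31 and 47 (cue under 6J) and 178 and 331 (shock and cue under 6J). There the cue log2 fold changes under 6J were reversed for Hspb1 in DH (0.82 reported, -0.04 here) and, in VH, for Pdia3 (0.26 reported, 0 to 2 decimals here) and Hyou1 (0.28 reported, -0.01 here); the cause was not tested.

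Without the DH library 40A, region by strain had 2 genes in place of 1; the cause was not tested. With an estimated correlation 23 of 775 gene list tests passed, in place of 196, and at a threshold of 0.01, which is stricter, 542 genes were shared by the DH and VH strain differences in place of 1219.

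DH and VH libraries with the same code did not meet the criterion for pairing, a correlation of deviations over 0.1 for every code: over 36 codes the median was 0.095, the lowest -0.189, and 16 were over 0.1. For 17 codes the DH library correlated best with the VH library of its own code among the 6 of its group, where chance gives 6 of 36, a hint from the data and not the design. With the code as a replicate block, 13319 genes differed between regions, 1 gene by strain and 14 by shock and cue, in place of 12888, 1 and 0. Depth, at 30330382 counts or more in a library, limits the genes with few counts that the filter removes.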

Other observations

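The test of brain temperature in this part was chosen after the results were seen, and the gene lists were fixed beforehand.

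Receptor subunits divided between the regions. Of 22 glutamate receptor genes, 10 were higher in DH and 11 in VH, with the same counts adjusted over the list alone. The NMDA receptor subunits Grin1 (0.22 ± 0.0212), Grin2a (0.44 ± 0.0258) and Grin2b (0.27 ± 0.0319) and the AMPA receptor subunit Gria1 (0.27 ± 0.0246) were higher in DH (log2 fold change, DH over VH, ± SE). Grin2d (-0.42 ± 0.0361), Gria4 (-0.57 ± 0.0335), the metabotropic receptor Grm8 (-0.56 ± 0.0676) and the kainate receptor subunits Grik1 (-0.64 ± 0.0407) and Grik4 (-0.4 ± 0.0346) were higher in VH. Of 19 genes of GABA signalling, 9 were higher in each region, again the same adjusted over the list alone. The subunit of extrasynaptic GABA-A receptors Gabrd was at 0.52 ± 0.045 and Gabra4 at 0.26 ± 0.0242, while Gabra3 was at -0.99 ± 0.0477. Neither list passed camera (adjusted p = 0.632 and 0.804).

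Immune and mitochondrial genes differed between the regions as well. Of 11 microglia markers 10 were higher in DH, also adjusted over the list alone, by small amounts such as 0.21 ± 0.047 for C1qa and 0.24 ± 0.0402 for Trem2 (camera adjusted p = 0.0551). Of 19 genes of interferon response and antigen presentation 11 were higher and 0 lower in DH, 10 adjusted over the list alone, with B2m at 0.38 ± 0.0287 and H2-D1 at 0.39 ± 0.0378 (camera adjusted p = 0.0445, and adjusted p = 0.778 with an estimated correlation). Of 15 mitochondrially encoded genes 13 were lower in DH, also adjusted over the list alone, with mt-Nd5 at -0.22 ± 0.0381 (camera adjusted p = 0.0636), and of 36 complex I subunits 29 were lower, with 29 lower and 2 higher adjusted over the list alone (adjusted p = 0.00257, and adjusted p = 0.778 with an estimated correlation). Of 10 neocortical markers 2 were higher and 6 lower in DH, also adjusted over the list alone, with Fezf2 at -0.7 ± 0.0402 and Ccn2 at -1.29 ± 0.135 (camera adjusted p = 0.0935). Of 9 striatal markers 4 were higher and 3 lower, also adjusted over the list alone, with the peptide genes Penk at 0.77 ± 0.0729 and Tac1 at -0.62 ± 0.0542 (camera adjusted p = 0.975).

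A hypothesis about temperature was tested in the responses to the cue and to shock and cue. Cirbp, a cold-inducible gene, was lower than in the home cage in 8 of 8 comparisons and passed edgeR in 7 of them, with log2 fold changes from -0.69 to -0.36, and the heat-inducible chaperone gene Dnajb1 passed as higher in 8 of 8, from 0.34 to 0.58. Of other heat-inducible genes, Hspa8, Hsph1 and Hsp90aa1 passed as higher in 4 of 8 each. Hspa1b passed in 1 and Hspa1a in 0 (-0.18 to 0.42). The 8 comparisons are not independent, since cue and shock and cue share a home cage group and DH and VH carried the same codes. A warmer brain in active mice could lower cold-inducible RNA-binding protein mRNAs together. Rbm3, the other such gene, fell with adjusted p under 0.05 in 0 of 8 comparisons, with log2 fold changes from -0.12 to 0.12. Cirbp and Rbm3 therefore did not fall together. Whether brain temperature changed cannot be decided from this, since the prediction covered only a change that lowers both mRNAs and no temperature was available.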
